A study of Mus musculus with 6 samples.

How the data were processed

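RNA was measured by sequencing in 6 libraries of the mouse mast cell line MC/9. Mast cells are tissue-resident immune cells that store histamine and proteases in granules. Per the series' design text, osteoblasts of the mouse line 7F2 were seeded first, mast cells were added a day later, the co-culture was exposed to rPTH at 10 nM for 24 h, and the mast cells were then collected. The labels do not spell out rPTH; it was read here as a parathyroid hormone preparation, the hormone that acts on bone through the receptor Pth1r. The labels mark 3 libraries as control and 3 as rPTH. They do not state whether the control mast cells had also been grown on osteoblasts. Per the labels' protocols, RNA was taken with Trizol and libraries were built with an Illumina TruSeq RNA kit; the strand setting of the counting is not given in the sources used here.

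The count of each gene in each library is a whole number in the table the authors deposited, with a different total per library and no normalization. Per the submitters' processing notes, which give names without roles or order, the tools were Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.0p3 with featureCounts, and DESeq2 1.12.4 in R 3.3.0. The same notes name both GRCm38.p5 and mm9; the annotation used for counting is not given in the sources used here. The authors also deposited a normalized signal table, in which each library's counts are divided by 1 size factor (0.7739 to 1.236), and a table of regularised log2 values, which was read only to learn its unit. The authors' deposited comparison table holds a mean signal, a log2 fold change with its standard error, a score that is the Wald statistic, and a p-value with its adjusted form for each gene. From that table the calls and folds of the authors are quoted as such and no error or n was added.

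Some reads were counted at more than 1 gene. The mitochondrial gene mt-Co2 had 39364 counts in control 1 and Gm28661, an unprocessed pseudogene on chromosome 1, had 39372. Of 15624 genes with a summed count of at least 100 over the 6 libraries, 40 shared all 6 counts with another gene. Counts of pseudogenes and of genes with near-identical copies, which include ribosomal protein genes, histones and mitochondrial genes, are therefore uncertain, as are those of overlapping genes, and library totals count some reads more than once.

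Total counts were 24387242, 24993606 and 22282095 in control 1, 2 and 3, and 30623648, 32953708 and 33577977 in rPTH 1, 2 and 3, so that every rPTH library was deeper than every control. A count of 0 in a library allows up to 3 counts, which is 0.135 CPM (counts scaled by library total) at the lowest depth and 0.0893 CPM at the highest. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries was a duplicate: a chi-square of their counts per degree of freedom ran from 13.3 to 291. Nothing in the labels says that the replicates came from separate cultures, so p-values here measure only the spread between these samples, which may be technical.

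Genes were tested with edgeR 4.0.16 (quasi-likelihood test, robust, TMM factors, Benjamini-Hochberg adjustment, adjusted p threshold 0.05) in R 4.3.3. The edgeR filter filterByExpr with its minimum count of 10 left 16696 of 49568 genes. Levels are given as CPM scaled by the TMM factors, as mean ± SD over 3 libraries per group, and log2 fold changes are rPTH minus control with the standard error of the fit. Sums over a gene list are in plain CPM. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which compares a list with all other tested genes; lists with at least 5 tested members entered, 23 of 24. Camera was repeated with an estimated correlation, and fry tested whether a list's members moved, on balance, in 1 direction. Among the lists called at the preset correlation the estimates ran from 0.089 to 0.98. They were 0.49 for osteoblast and stromal markers, 0.96 for oxidative phosphorylation and 0.98 for ribosomal proteins. The preset value assumes far less shared movement, so camera's adjusted p at that value overstates the evidence for such lists. The summed CPM of osteoblast and stromal markers was compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 libraries against 3.

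The groups, the tests, the lists, the alternatives and the rule for named genes were set before the data were examined, except where an alternative is said to be chosen after seeing the data. The lists covered mast cell identity, granule proteases, mediators, cytokines, growth factors, cAMP and parathyroid hormone responses, markers of osteoblasts, adipocytes, macrophages and lymphoid or erythroid cells, cell cycle, stress and metabolic programs, and mitochondrial, ribosomal protein and histone transcripts. By the rule, the text names up to 10 rising and 10 falling genes past the threshold with a mean of at least 1 CPM and groups that do not overlap. With fewer than 5 such genes, it names the 5 rising and 5 falling genes of smallest unadjusted p at that mean, as values that did not pass. It also names 14 genes fixed by name and, from each list with no member past the threshold, the member of smallest unadjusted p. Other genes are said to be chosen after their values were seen.

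Alternatives were DESeq2 size factors, upper-quartile factors, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, edgeR without robust, other thresholds, a replicate block and leaving out each library. Gene positions, biotypes, transcript lengths and GC content came from GENCODE release M21 on GRCm38, matched by gene symbol, since the deposited tables hold no coordinates; 16203 of the tested genes (97%) had a length. Length and GC content were those of the longest annotated transcript of each symbol, which need not be the one expressed. Length and GC trends were removed with a loess fit of each library's log2 deviation (span 0.5, prior count 2). On simulated counts for rPTH against control over 16489 genes, the test recovered 14% of 100 genes changed 2-fold and 76% of 100 changed 4-fold. Of the 99 genes it called there, 8 had not been changed. With no change simulated it called 0 genes. Genes were drawn independently and without trends of single libraries, so these rates need not hold for the real counts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.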

Results

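The transcriptome of MC/9 mast cells was compared between 3 control libraries and 3 libraries from cells exposed to rPTH at 10 nM for 24 h in culture with osteoblasts. Counts covered 49568 genes, and each library detected 25880 to 31346 of them at total counts of 22282095 to 33577977. Some mast cell transcripts were abundant: the high-affinity IgE receptor chain Fcer1a had 1600 ± 407 CPM in controls and 1370 ± 267 CPM with rPTH (SD, n = 3 each), and the granule protease Cpa3 had 2120 ± 449 and 1870 ± 252 CPM. Control 1 stood apart from the other 5 libraries on the first principal component (53.1% of the variance) and control 3 on the second (31.1%).

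The first question was which single genes differed between rPTH and control. Thbs2, which encodes the matrix glycoprotein thrombospondin 2, had 185 ± 4.57 CPM in controls and 340 ± 71.9 CPM with rPTH (SD, n = 3 each), a log2 fold change of 0.88 ± 0.20 (SE). Ptgfr, the prostaglandin F receptor, had 2.23 ± 0.245 and 5.26 ± 1.49 CPM, and Pde8a, a phosphodiesterase that breaks down cAMP, had 2.18 ± 0.204 and 4.62 ± 0.697 CPM. Igsf10, an immunoglobulin superfamily member, had 1.86 ± 0.672 and 5.34 ± 1.16 CPM, and Olfr56, annotated as an olfactory receptor gene, had 5.16 ± 0.617 and 9.57 ± 0.637 CPM. On the lower side, Cecr2, a chromatin remodelling factor, had 2.96 ± 2.28 CPM in controls and 0.421 ± 0.0899 CPM with rPTH, with 144 of its counts in control 2 against 39 in control 1 and 31 in control 3. The other 4 genes of smallest p on that side were processed pseudogenes: Gm7079 (11.4 ± 3.46 and 3.96 ± 0.603 CPM), Gm11694 (7.89 ± 1.49 and 3.38 ± 0.297 CPM), Gm10059 (14.3 ± 4.7 and 5.69 ± 0.697 CPM) and Gm13827 (22.1 ± 5.4 and 11.1 ± 0.833 CPM). For all 10 genes the 3 rPTH libraries lay on 1 side of the 3 controls. The log2 fold changes of the 4 pseudogenes were -1.53 (Gm7079), -1.22 (Gm11694), -1.33 (Gm10059) and -0.99 (Gm13827). After removal of each library's length and GC trend, chosen after seeing the data, they were -0.62, -0.51, -0.43 and -0.29. That of Cecr2 was -2.81 before and -3.14 after.

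None of these genes passed the test: with edgeR, 0 of 16696 genes had an adjusted p under 0.05 and the smallest adjusted p was 0.619. An unadjusted p under 0.05 was reached by 1314 genes (7.9%), 331 higher and 983 lower with rPTH. The count was 272, 584 and 507 without rPTH 1, 2 and 3 and 2165, 2098 and 1638 without control 1, 2 and 3, and 525 with a replicate block. The balance also depended on the setting: 25.2% of such genes were higher here, 46.5% after removal of each library's length and GC trend and 66.9% among protein-coding genes alone, the last 2 settings chosen after seeing the data. DESeq2 and limma-voom also called 0 genes, with 1995 and 863 genes at an unadjusted p under 0.05. The groups did not overlap for 2806 genes (16.8%, against 10% by chance). Genes move together by library, so this share can lie above 10% without an effect of rPTH. Among the 983 lower genes 778 were processed pseudogenes, against 2666 of all 16696 tested genes. This class had 98400 CPM in control 3 and 123000 CPM in control 1 against 71000 to 80800 CPM in the other 4 libraries. Among the 331 higher genes 0 were processed pseudogenes and 13 were on the osteoblast and stromal marker list, which had 35 tested members. With control 2 as the only control left, an alternative chosen after seeing the data, edgeR called 2 lower genes, Cecr2 and Fgf12 (adjusted p = 0.0109 each); Fgf12 was named after its value was seen.

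In GENCODE M21 on GRCm38, Thbs2 spans chromosome 17 from 14665500 to 14694235, Ptgfr chromosome 3 from 151796502 to 151837630, Pde8a chromosome 7 from 81213596 to 81334533 and Igsf10 chromosome 3 from 59316735 to 59344394. Olfr56 spans chromosome 11 from 48978889 to 49135387 on the same strand as the interferon-inducible gene Ifi47, which it overlaps. Ifi47 had 52 ± 19.3 CPM in controls and 49.9 ± 2.63 CPM with rPTH. On the other strand Olfr56 overlaps Tgtp1, Tgtp2, Gm12185, Olfr1396, 9930111J21Rik1 and 9930111J21Rik2, Igsf10 overlaps Med12l, Gm10059 overlaps Letm1 and Gm13827 overlaps Sppl3. The strand setting of the counting is not given in the sources used here, so reads of these genes are not excluded from the counts. Cecr2 spans chromosome 6 from 120666369 to 120771190. The pseudogenes lie on chromosome X from 8047229 to 8047399 (Gm7079), chromosome 11 from 115493024 to 115493182 (Gm11694), and chromosome 5 from 33759366 to 33759536 (Gm10059) and from 115053469 to 115053840 (Gm13827). Reads of such copies cannot be told from those of their parent genes where the sequences are near-identical, so these counts are uncertain.

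The authors' deposited table gave 11 genes an adjusted p under 0.05, 5 higher and 6 lower with rPTH. In the authors' deposited table the 5 higher genes were Olfr56 (log2 fold change 0.9), Ifi44 (1.14), Thbs2 (0.89), Pde8a (1.04) and Igsf10 (1.3). The 6 lower genes in the authors' deposited table were Cecr2 (log2 fold change -1.73) and the processed pseudogenes Gm7079 (-1.25), Gm11694 (-1.03), Gm8692 (-1.37), Gm16106 (-1.48) and Gm20302 (-1.32). The adjusted p of these 11 in the authors' deposited table ran from 0.0479 to 0.0498. On the deposited counts, DESeq2 1.42.0 called 0 genes, with a smallest adjusted p of 0.0567, and 0 genes with its older shrinkage prior, chosen after seeing the data, with a smallest adjusted p of 0.0528. These lie just above the threshold. With the prior the log2 fold changes were 0.9 for Olfr56, 1.14 for Ifi44, 0.89 for Thbs2, 1.04 for Pde8a, 1.3 for Igsf10 and -1.74 for Cecr2, close to those of the authors.

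The receptors for parathyroid hormone were near the limit of detection. Pth1r had 10 to 19 counts per library, 0.456 ± 0.0619 CPM in controls and 0.463 ± 0.0937 CPM with rPTH (log2 fold change 0.03 ± 0.37, SE), and Pth2r had 0 to 3 counts and was too low to test. The stem cell factor receptor Kit had 494 ± 187 and 510 ± 53.5 CPM, and the histamine-forming enzyme Hdc had 644 ± 133 and 550 ± 76.8 CPM. Among cytokines, Il6 had 15.7 ± 0.882 and 16.1 ± 2.51 CPM and Tnf 24.1 ± 3.91 and 19.3 ± 3.38 CPM. The angiogenic factors Vegfa (79.3 ± 4.75 and 102 ± 22.6 CPM) and Angpt1 (35.9 ± 11.9 and 49.3 ± 3.09 CPM) had all 3 rPTH libraries above the controls, and Tgfb1 (270 ± 58.7 and 205 ± 11.7 CPM) had all 3 below. Angpt2 had 0.831 ± 0.305 and 0.873 ± 0.266 CPM and Pdgfa 31.2 ± 11.2 and 26.6 ± 5.18 CPM. In edgeR the adjusted p of these genes, Fcer1a, Cpa3 and Col1a1 included, ran from 0.628 to 0.977 and none passed. The sign of the fold change of Pth1r, Kit, Fcer1a, Cpa3, Il6, Angpt2 and Pdgfa differed between alternatives. The log2 fold changes of Vegfa (0.36), Angpt1 (0.46) and Tgfb1 (-0.39) kept their signs but varied in size. Without single libraries they ran from 0.17 to 0.47, from 0.2 to 0.71 and from -0.43 to -0.22.

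The next question was whether gene lists set beforehand moved between the groups. Osteoblast and stromal marker transcripts summed to 2860, 3110 and 3040 CPM in control 1, 2 and 3 and to 6060, 3990 and 4110 CPM in rPTH 1, 2 and 3. The means were 3000 ± 127 CPM in controls and 4720 ± 1160 CPM with rPTH (SD, n = 3 each), 1.57 times as high; the exact two-sided permutation test of the 1720 CPM difference gave p = 0.1, the smallest this design allows. Of 35 tested markers 34 had a log2 fold change above 0, with a median of 0.54, and 17 had all 3 rPTH libraries above the controls. The matrix cross-linking enzyme Lox had 48.3 ± 7.34 and 94.5 ± 26.5 CPM and the collagen chain Col1a1 155 ± 15.5 and 217 ± 72.1 CPM. The list was higher with rPTH in camera (adjusted p = 5.61e-15 at the preset correlation; adjusted p = 0.593 with an estimated correlation), while 0 members passed over all genes and 0 adjusted over the list alone. Without rPTH 1 the difference in summed CPM was 1050 and the median log2 fold change 0.29.

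**Figure D1:**
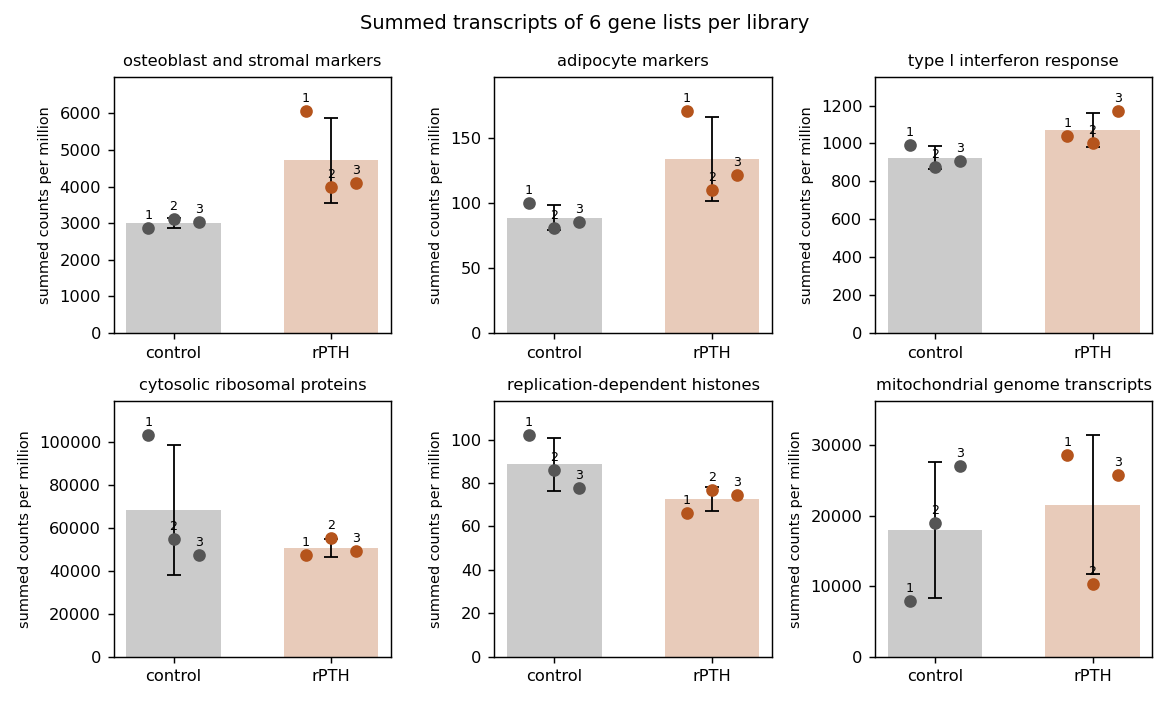
Summed CPM (vertical axes, from 0) of 6 gene lists in each library, with bars for group means, error bars for SD (n = 3) and points numbered by replicate. The osteoblast and stromal markers reach 6060 CPM in rPTH 1 against 2860 to 3110 CPM in the controls, and ribosomal protein transcripts reach 103000 CPM in control 1 against 47200 to 55100 CPM in the other libraries.

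Another 6 lists were higher with rPTH at the preset correlation but none of them with an estimated correlation, and none of their members passed over all genes or adjusted over the list alone. Type I interferon response genes had 20 of 29 members above 0 (median log2 fold change 0.32, camera adjusted p = 0.000172; adjusted p = 0.593 with an estimated correlation). Ifi44, an interferon-induced gene, had 2.61 ± 0.65 CPM in controls and 6.04 ± 1.08 CPM with rPTH (SD, n = 3 each). In plain CPM the list summed to 992, 874 and 909 in control 1, 2 and 3 and to 1040, 1000 and 1170 in rPTH 1, 2 and 3. The TMM factor was 0.81 in control 1 and 1.03 to 1.06 in the other libraries. With TMM scaling the sum was therefore highest in control 1. Whether all rPTH libraries lie above all controls thus depends on the scaling. TGF-beta and matrix response genes had 17 of 27 members above 0 (median 0.20, adjusted p = 0.00251), with the metalloproteinase inhibitor Timp3 at 8.59 ± 2.37 and 17.9 ± 5.26 CPM. Angiogenic and growth factors had 19 of 29 above 0 (median 0.18, adjusted p = 0.00432), with hepatocyte growth factor Hgf at 2.97 ± 1.37 and 6.7 ± 1.81 CPM. The genes that respond to parathyroid hormone in osteoblasts had 16 of 21 above 0 (median 0.33, adjusted p = 0.00377), with the prostaglandin synthase Ptgs2 at 62.2 ± 14.7 and 109 ± 33.1 CPM; 3 of that list's genes and 1 of the TGF-beta list were also on the stromal marker list. Adipocyte markers had 5 of 6 above 0 (median 0.42, adjusted p = 0.00377), with the acyl-CoA synthetase Acsl1 at 20.2 ± 2.49 and 28.8 ± 4.33 CPM. Only these 6 of the 15 adipocyte markers were high enough to test, so the list says little about adipocytes. Genes of the cAMP and CREB response had 19 of 30 above 0 (median 0.08, adjusted p = 0.0421), with the kinase Sgk1 at 19.7 ± 3.5 and 32.6 ± 10.3 CPM.

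With an estimated correlation the adjusted p was 0.593 for 5 of these 6 lists and 0.675 for the cAMP list. Library rPTH 1, which had the most stromal marker transcripts, also had the highest sum of the TGF-beta list (2200 CPM against 1940 and 1870 in rPTH 2 and 3), of the growth factors (968 against 790 and 800), of the osteoblast response genes (1440 against 1210 and 1190) and of the adipocyte markers (171 against 110 and 122). Without control 3 the calls of the growth factors (adjusted p = 0.0729), cAMP genes (0.0729), osteoblast response genes (0.0716), adipocyte markers (0.0716) and TGF-beta list (0.0874) ended. Their medians were not smaller (0.18, 0.28, 0.33, 0.46 and 0.22 in that order). The ended calls therefore do not show that control 3 carried the shifts of these members. Camera also depends on the other tested genes, which control 3 can move, so control 3 may still have carried the calls. Without rPTH 1 the medians fell to 0.04 for the growth factors, 0.03 for the cAMP genes, 0.14 for the osteoblast response genes, 0.20 for the adipocyte markers and 0.13 for the TGF-beta list. Without rPTH 3 that of the interferon list fell to 0.11 and its call stayed (adjusted p = 0.0213; range over all alternatives 4.1e-12 to 0.593). Without control 1 the medians were 0.29, 0.02, 0.18, 0.63 and 0.34 for the same 5 lists. The call of the cAMP genes also ended without control 1 (0.43) and without rPTH 1 (0.134). It ended with at least 1 CPM in 3 libraries (0.0773) and among protein-coding genes (0.202, median 0.09) as well. That of the adipocyte markers ended without control 2 (0.0976, median 0.33) and without the low-count filter (0.0611, median 0.55). With control 2 as the only control, chosen after seeing the data, the median was -0.01 for the cAMP genes and 0.13 for the osteoblast response genes. Over all alternatives the adjusted p ran from 0.000453 to 0.593 for the growth factors, 0.000768 to 0.879 for the cAMP genes, 0.000879 to 0.593 for the osteoblast response genes, 8.15e-06 to 0.593 for the adipocyte markers and 4.85e-07 to 0.593 for the TGF-beta list.

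Transcripts of 4 lists were lower with rPTH at the preset correlation. None of the 4 calls held with an estimated correlation: adjusted p = 0.857 with an estimated correlation for ribosomal proteins and oxidative phosphorylation, 0.593 for histones and 0.784 for proteases. All 75 tested cytosolic ribosomal protein genes had a log2 fold change below 0 (median -0.66, camera adjusted p = 1.41e-09), as had 50 of 52 oxidative phosphorylation subunits (median -0.59, adjusted p = 1.17e-05) and all 19 replication-dependent histones (median -0.76, adjusted p = 0.00016). Granule proteases had 16 of 17 members below 0 (median -0.30, adjusted p = 0.00786), with the mast cell protease Mcpt2 at 1.02 ± 0.151 CPM in controls and 0.28 ± 0.117 CPM with rPTH (SD, n = 3 each), from only 5 to 30 counts per library. Examples of the other lists were Rpl24 (35.5 ± 18.1 and 15.8 ± 1.57 CPM), Atp5d (206 ± 121 and 117 ± 2.15 CPM) and Hist1h1d (1.86 ± 0.0815 and 1.02 ± 0.122 CPM). No member of these lists passed over all genes or adjusted over the list alone.

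These 4 calls ended without control 1, in which ribosomal protein transcripts summed to 103000 CPM against 54800 and 47200 CPM in control 2 and 3 and 47300 to 55100 CPM in the rPTH libraries. Without control 1 the adjusted p was 0.26 for ribosomal proteins, with a median of -0.06, 0.0914 for histones, with a median of -0.38, 0.825 for oxidative phosphorylation, with a median of -0.01, and 0.164 for proteases, with a median of -0.09. The protease call also ended without control 2 (adjusted p = 0.107) and without rPTH 1 (0.0529), with medians of -0.44 and -0.29 that do not show these libraries carried the shift. After removal of each library's length and GC trend, chosen after seeing the data, oxidative phosphorylation (adjusted p = 0.0533, median -0.18) and histones (0.0601, -0.3) no longer passed. Ribosomal proteins (0.00139, -0.25) and proteases (0.0309, -0.22) kept their calls with smaller medians. With control 2 as the only control, also chosen after seeing the data, ribosomal proteins (adjusted p = 1.15e-06, median -0.15), oxidative phosphorylation (0.0135, -0.07) and histones (1e-04, -0.41) passed and proteases (0.0518) did not. Over all alternatives the adjusted p ran from 1.8e-23 to 0.857 for ribosomal proteins, 3.47e-13 to 0.857 for oxidative phosphorylation, 8.88e-09 to 0.593 for histones and 0.000143 to 0.784 for proteases.

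**Figure D2:**
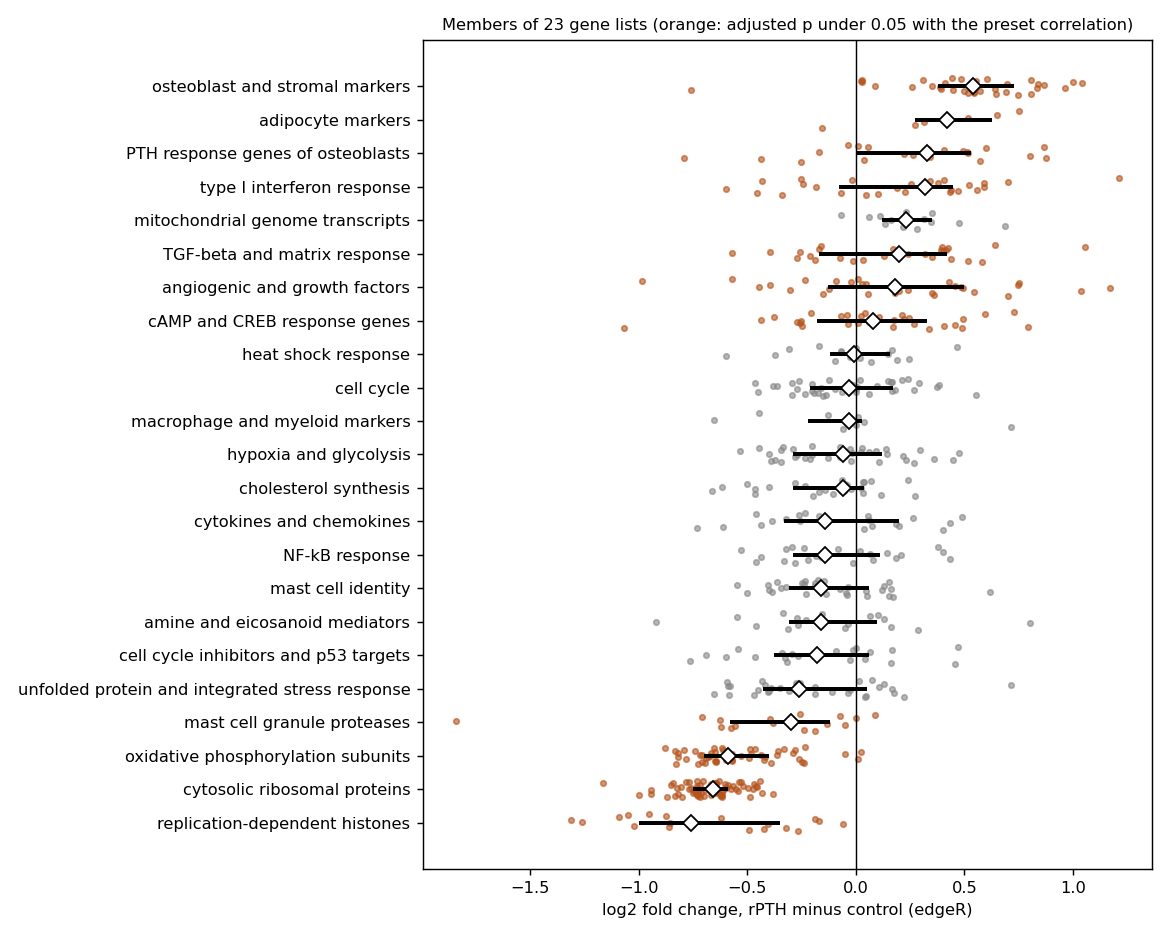
Log2 fold changes (horizontal axis, rPTH minus control, edgeR) of the tested members of 23 gene lists, 1 point per gene, with the median as a diamond and the interquartile range as a bar; orange lists had an adjusted p under 0.05 at the preset correlation. Medians run from -0.76 for histones to 0.54 for osteoblast and stromal markers.

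The other 12 tested lists did not pass at the preset correlation, though some did in single alternatives. Mast cell identity genes had 21 of 30 members below 0 (median log2 fold change -0.16, camera adjusted p = 0.515), with the integrin chain Itgb7 at 273 ± 63.4 CPM in controls and 207 ± 17.9 CPM with rPTH (SD, n = 3 each). Mediator genes had a median of -0.16 (adjusted p = 0.76), and genes of the unfolded protein and integrated stress response -0.26 (0.0694), with the pseudokinase Trib3 at 28.3 ± 6.5 and 18.8 ± 0.686 CPM. Without control 1 the median of the stress response was -0.05. The list passed without rPTH 1 (adjusted p = 0.042), with at least 1 CPM in 3 libraries (0.0351) and among protein-coding genes (0.00258). Its range over all alternatives was 0.00258 to 0.857. Medians were -0.18 for cell cycle inhibitors and p53 targets (adjusted p = 0.566), with Bbc3 at 19 ± 5.46 and 11.2 ± 0.684 CPM, and -0.14 for NF-kB response genes (0.996). For cholesterol synthesis the median was -0.06 (0.455), with Fdps at 25 ± 9.25 and 15.8 ± 0.369 CPM. Without single libraries the medians ran from -0.21 to -0.05 for mast cell identity and -0.21 to -0.09 for mediators. They ran from -0.22 to -0.09 for cell cycle inhibitors and p53 targets, -0.19 to 0 for NF-kB and -0.13 to 0.08 for cholesterol synthesis. Mitochondrial genome transcripts had a median of 0.23 (adjusted p = 0.0676), with mt-Atp8 at 16.6 ± 9.56 and 26.8 ± 11 CPM. Single libraries set that median: it was -0.09 without control 1, -0.04 without rPTH 1, 0.66 without control 3, 0.59 without rPTH 2 and 0.09 without rPTH 3. The sum of these transcripts was 7850 CPM in control 1 and 10300 CPM in rPTH 2 against 18900 to 28600 CPM in the other libraries.

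In 5 lists the camera direction was higher while the median and the mean log2 fold change lay below 0. Camera compares a list with all tested genes, whose median was -0.087. They were cytokines (median -0.14, below that median too, adjusted p = 0.974), cell cycle (-0.03, 0.515), hypoxia and glycolysis (-0.06, 0.934), macrophage markers (-0.03, 0.955) and heat shock genes (-0.01, 0.455). With DESeq2 size factors the medians of the last 4 lists lay above 0. Without control 1 the median of the cytokines was 0.06, and those of the last 4 lists ran from 0.01 to 0.13. Their examples were the chemokine Ccl3 (27.5 ± 7.97 CPM in controls and 19.9 ± 3.69 CPM with rPTH), the cyclin Ccnd1 (55 ± 2.54 and 80.7 ± 17.4 CPM), Ddit4 (31.2 ± 1.41 and 23.8 ± 1.53 CPM), Mpeg1 (2.24 ± 0.626 and 3.69 ± 0.765 CPM) and the chaperone Hspa4l (122 ± 39.5 and 169 ± 24.5 CPM). Lymphocyte and erythroid markers had only 4 tested members and were not tested as a list; Hba-a1 had 2.1 ± 1.37 and 1.3 ± 0.124 CPM. None of the members named for these lists passed in edgeR, with adjusted p from 0.619 to 0.635.

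**Figure D3:**
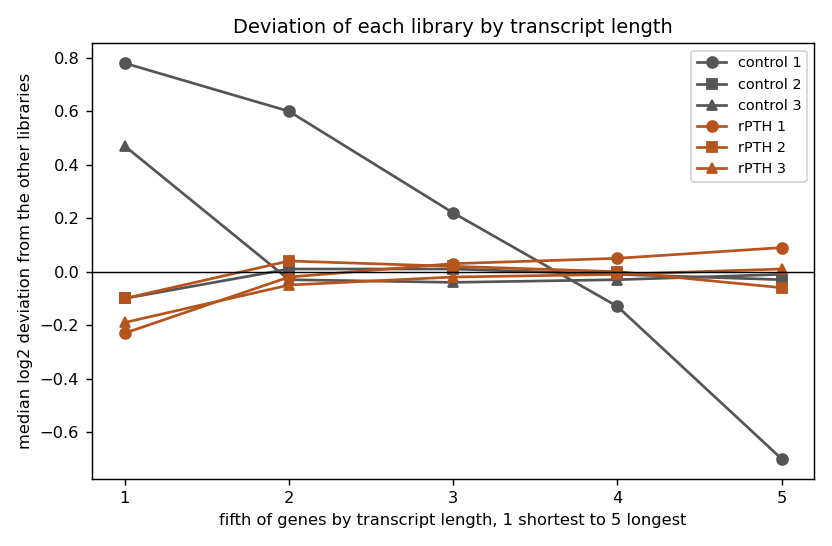
Median log2 deviation of each library from the mean of the others (vertical axis; control 1 is left out of the mean used for the other libraries) in 5 groups of genes from the shortest to the longest transcripts (horizontal axis), without ribosomal protein genes. Control 1 runs from 0.78 in the shortest to -0.70 in the longest group, and control 3 lies at 0.47 in the shortest.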

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

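Chosen only after seeing the data were removal of the length and GC trend, thinning to equal depth, leaving out control 1 and 3 together, protein-coding genes alone and DESeq2 with its shrinkage prior. With edgeR 0 genes passed, and 0 in 20 alternatives; 2 passed without control 1 and 3, where the lone control is assumed to vary like the others, and 1314 had an unadjusted p under 0.05. Without the low-count filter the median of all genes moved by 0.129 on the log2 scale; other scalings moved it by less than 0.1. The osteoblast marker difference stayed above 0, from 1050 to 2080 CPM without single libraries. The 11 list calls became 0 with an estimated correlation and 0 with fry, and 7 to 12 without single libraries (7 without control 3). The replicate numbers did not pair the samples (correlations -0.13, -0.32 and 0.14; control 1 and control 2 correlated best with other numbers); with a replicate block 0 genes and 11 lists passed and the marker difference was 1720 CPM. Calls gained beyond the 11 had these adjusted p: without the filter, cytokines 0.0162, cell cycle 0.0162, heat shock 0.0342 and mitochondrial transcripts 0.013; with 1 CPM in 3 libraries, stress response 0.0351; with the trend removed, cholesterol 0.0098 and mitochondrial 0.00291; with protein-coding genes, stress response 0.00258; without control 1 and 3, mast cell identity 0.0297 and cytokines 0.0062; without control 1, cytokines 0.00156, heat shock 0.00391 and cholesterol 0.0101; without control 3, mitochondrial 0.00556; without rPTH 1, stress response 0.042; and without rPTH 2, mitochondrial 1.39e-05. A list was counted as turned by the direction of its own test, a rule set after a first output by medians had given fewer turns. Directions of lists outside the 11 calls turned with these adjusted p: without the filter, mast cell identity 0.72, mediators 0.404, macrophage markers 0.248 and NF-kB 0.248; with 1 CPM in 3 libraries, cytokines 0.915; with fry, which compares with 0, cytokines 0.817, macrophage 0.796, cell cycle 0.919 and hypoxia 0.796; with protein-coding genes, cytokines 0.501, macrophage 0.755, cell cycle 0.782 and hypoxia 0.501; thinned, macrophage 0.997; with the trend removed, cell cycle 0.669, hypoxia 0.79 and NF-kB 0.451; without control 1 and 3, cell cycle 0.967; and NF-kB 0.91 with DESeq2 size factors, 0.974 with upper-quartile factors and 0.978 with the block. Without single libraries the lists named next turned, each turn at an adjusted p of 0.654 or more, mitochondrial transcripts (0.985) and oxidative phosphorylation (0.825) without control 1 alone. Over all 6 such fits, turned or not, the adjusted p ran from 0.0795 to 0.967 for mast cell identity, 0.541 to 0.988 for mediators, 0.00156 to 0.991 for cytokines, 0.526 to 0.988 for macrophage markers, 0.133 to 1 for hypoxia, 0.767 to 0.918 for NF-kB, 1.39e-05 to 0.985 for mitochondrial transcripts and 3.47e-13 to 0.825 for oxidative phosphorylation. Log2 fold changes that turned sign were -0.01 for Pth1r with limma-voom; -0.09 for Kit, -0.09 for Il6 and -0.02 for Angpt2 with the trend removed; and -0.24 for Kit, 0.05 for Fcer1a, 0.04 for Cpa3 and -0.42 for Angpt2 without control 1 and 3. Over the 6 fits without single libraries, log2 fold changes ran from -0.12 to 0.17 for Pth1r, -0.25 to 0.27 for Kit, -0.1 to 0.11 for Il6, -0.18 to 0.37 for Angpt2 and -0.4 to 0.06 for Pdgfa. Of the other log2 fold changes of named genes, 831 kept their sign and side of the threshold and 1 passed, that of Cecr2 without control 1 and 3. The cause of these turns was not tested. Low counts limit Pth1r (10 to 19), Pth2r (0 to 3) and Mcpt2 (5 to 30).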

Other observations

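The tests of osteoblast RNA, of transcript length in control 1, of ribosomal protein genes taking counts from the rest, of pseudogenes against parent genes, of genomic DNA and of other splits for the count of genes were chosen only after the result was seen. The genes of the next paragraph were also chosen after their values were seen.

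Among the most abundant transcripts were the common beta chain of the receptors for interleukin-3, interleukin-5 and GM-CSF, Csf2rb (3970 ± 839 CPM in controls and 3610 ± 377 CPM with rPTH; SD, n = 3 each) and the interleukin-3 receptor beta chain Csf2rb2 (2880 ± 616 and 2600 ± 296 CPM). Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, had 3510 ± 342 and 2910 ± 346 CPM. Control libraries also carried transcripts of osteoblasts and stromal cells: osteopontin Spp1 had 537 ± 194 CPM in controls and 665 ± 164 CPM with rPTH, biglycan Bgn 466 ± 94.8 and 633 ± 157 CPM, and fibronectin Fn1 425 ± 158 and 758 ± 232 CPM. The lipase Lpl, on the adipocyte marker list, had 34.1 ± 9.19 and 53.5 ± 15.2 CPM. None of these genes passed in edgeR.

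Osteoblast and stromal markers lay above the control mean by a median log2 of 0.91 in rPTH 1, 0.28 in rPTH 2 and 0.32 in rPTH 3. A length and GC trend between libraries, as fitted on the longest annotated transcripts, was argued against as the cause. After its removal the lower quartile of the markers' log2 fold changes was 0.32 (0.39 before). The list kept its camera call at the preset correlation (adjusted p = 4.73e-19). Without the removal that call was lost with an estimated correlation (adjusted p = 0.593). A larger share of osteoblast RNA in the rPTH libraries stays open as a hypothesis. There were 318 genes outside the list with higher values at an unadjusted p under 0.05. For 94% of them rPTH 1 was the highest rPTH library (95% Clopper-Pearson interval 90.8 to 96.4), against 33.3% by chance and 41.4% of all tested genes. Genes are not independent replicates, so the interval does not measure the spread between libraries. They were also picked for a higher rPTH mean, which 1 high rPTH library favours, so 33.3% is not their expected share. A response to rPTH that was strongest in rPTH 1 could give the same order, and was not tested apart from it. Mast cell identity transcripts summed to 14400 CPM in rPTH 1 against 18300 and 18100 CPM in rPTH 2 and 3. Granule proteases summed to 4230 against 5700 and 5160 CPM. This order goes with a larger osteoblast share in rPTH 1, but a response that lowers these transcripts could give it too. Control 1 had a similar identity sum (14800 CPM) with the lowest stromal marker sum (2860 CPM), though its protease sum was 6440 CPM. A low identity sum thus also occurred without more stromal transcripts. Between the groups the identity sums were 17400 ± 2350 CPM in controls and 16900 ± 2220 CPM with rPTH. Blood cells can also express Fn1, Spp1, Sparc and Thy1, and without these 4 of the 41 markers the difference in summed CPM was 1090. Whether blood cells express other markers of the list was not tested.

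Control 1 stood apart, with ribosomal protein genes at a median log2 deviation of 1.43 from the other libraries. A few abundant ribosomal protein genes taking counts from the rest would lower other genes by 1 common factor. However, of 5 groups of these other genes by transcript length, the shortest and the longest differed by a median log2 of 1.47 (95% bootstrap interval 1.42 to 1.51). Processed pseudogenes, which can share reads with their parent genes, stayed among them and can raise the shortest group. The second shortest group had a median of 0.60 and the longest -0.70, so the difference did not rest on the shortest group alone. The length and GC trend as fitted was argued against as the whole cause, since the lower quartile of the ribosomal protein deviation was 0.70 after its removal (1.32 before). The fit took the longest annotated transcript of each gene, which can exceed the one expressed. A length trend as the whole cause was therefore not excluded. Recovery that depends on transcript length stays a candidate explanation for part or all of the deviation. The Spearman correlation of control 1's deviation with transcript length was -0.55 across genes, against -0.25 to 0.34 in the other libraries. Genes are not independent replicates. No biological explanation was tested, since control 1 shares its group with control 2 and 3.

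Control 3 had more counts on processed pseudogenes than control 2 and the rPTH libraries, and 31346 genes with a count at the lowest depth. Genomic DNA as the whole cause was argued against, if genomic reads are counted alike per kb on pseudogenes and lincRNA genes. Some reads were counted at more than 1 gene, so that condition may fail for copies. The genes compared had a mean of 10 to 50 counts, control 3 included, so genes could enter through the excess itself. In control 3 the excess was 2.85 CPM per kb on 1005 processed pseudogenes and 0.0323 on 160 lincRNA genes. The former less 2 times the latter was 2.78 (95% bootstrap interval 2.55 to 3.03). This difference replaced the ratio because the lincRNA interval spans 0 (-0.00887 to 0.0681). Reads placed on near-identical copies in place of their parent genes stay a candidate explanation. The median centred log2 ratio of pseudogene to parent was 0.70 over 336 pairs, against upper quartiles of -0.04 to 0.01 in the other libraries. In control 3 the pseudogenes' median log2 deviation from the mean of all libraries was 0.39. That of the parents was -0.27, near rPTH 3 (-0.23) and rPTH 1 (-0.18). Genomic DNA could raise the ratio too, so the ratio does not tell the 2 explanations apart. A smaller part from genomic DNA stays open, since control 3 also had counts on 1449 lincRNA genes against 954 to 1207 in the other libraries. No biological explanation was tested.

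The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes in edgeR and the highest of the others 0, so that 10 of 10 splits had as many, which a real count of 0 fixes in advance. At an unadjusted p under 0.05 the real split gave 1314 genes and the highest of the others 971, a count read only after the result was seen. The 1314 became 272, 584 and 507 without rPTH 1, 2 and 3 and 2165, 2098 and 1638 without control 1, 2 and 3. For gene lists at the preset correlation the real split gave 11 calls and the highest of the others 10, so that 1 of 10 splits had as many. The camera adjusted p of the osteoblast and stromal markers at the preset correlation was 5.61e-15 in the real split and at lowest 2.76e-11 in the others. With an estimated correlation it was 0.593 in the real split.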
